A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

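The data were a deposited table of RPKM values (reads scaled to gene length and library size) per the file headers, with 7126 genes in 12 libraries and decimal commas that were read as decimal points. The groups were wild type and slt2, each with and without 100 µg/ml poacic acid for 1 h, with 3 libraries each. Per the labels, cells were diluted to an OD of 0.2 and the compound was added at an OD of 0.5, libraries of 300 to 450 bp inserts were made from rRNA-depleted RNA with a strand-specific kit, and the build was R64. The growth text gives 2 h where the treatment text gives 1 h. The aligner, the counting program, whether reads were counted by strand and how reads with several matches were handled are not given in the sources used here. Values of genes that overlap another gene, and of near-identical copies such as ENA1 and its tandem copies, PHO12, HXT7, ribosomal protein pairs and histone pairs, are uncertain for that reason. No read files were used here.

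The unit was checked against the gene lengths. The values of each library were whole multiples of the value of 1 read, within a tolerance of 1%, for 95.0 to 95.1% of genes with gene spans and 99.1 to 99.2% with exon lengths. That gave totals of 3462651 to 10542488 reads per library (median 6671236.5), of which 72.4 to 80.1% (2670577 to 8305911) fell in listed genes. A floor of 3 reads in a gene of 1 kb was 0.285 to 0.866 RPKM, and 1 read was 0.095 to 0.289 RPKM. Genes above 0 numbered 6209 to 6323 per library. The 10 coding genes with the most reads took 16.9 to 20.0% of reads. Correlation between libraries of a group across genes was 0.982 to 0.984 (untreated wild type), 0.954 to 0.975 (treated wild type), 0.979 to 0.986 (untreated slt2) and 0.971 to 0.982 (treated slt2). Treated wild-type replicate 1 was closest to untreated wild-type replicate 3 (0.979). The leading components held 37.7%, 18.1% and 12% of the variance. Treated wild-type replicate 3 stood apart from its group on the first (9.3, against −12.5 and −19) and the third (−26.6, against −11.5 and −2.4), and it had the highest rRNA share of the group (5.15%). Between replicates of a group the chi-square per degree of freedom was 4.8 to 101.5, so no library was a copy of another.

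Genes reading at least 1 RPKM in at least 3 libraries were tested (6222). The plan held a test for counts and another for normalised values, and the latter was used as the table held RPKM. The values were taken as log2(RPKM + 1) and fitted with limma, with an intensity trend and robust variances, with 1 mean per group over all 12 libraries. Fold changes are on that scale, and they understate changes of genes with low values. Adjusted p always means limma p values with Benjamini-Hochberg correction over all tested genes (or over all 29 lists for a list), and 0.05 was the threshold. The wild-type and slt2 responses, their difference, and the strain differences without and with the compound were tested. Lists were tested by camera against all other genes with a preset correlation of 0.01, and again with a correlation estimated from the data. A list call always means camera. The planned fry test, for movement of a list and not against other genes, was run too. Its p values are unadjusted and are given for some lists. Counts adjusted over the list alone used the members of that list only. SLT2 was left out of its own lists. The tests, the lists, the settings and 18 other ways of processing were fixed before the data were examined, and 5 more were added after seeing the data. Wall integrity signalling, Slt2 and Rlm1 targets, glucan synthesis, wall remodelling, chitin, wall proteins, osmostress, general stress, ribosomal proteins, ribosome biogenesis, mating, glucose-repressed genes, respiration, iron, phosphate, drug resistance, oxidative stress, heat shock, unfolded protein response, calcineurin, G1/S, mitosis, histones, ergosterol, amino acid synthesis, sulfur, proteasome and mitochondrially encoded genes were 28 of the 29 tested lists, the last list is not reported here, and 2 more (markers and alpha-cell genes) served as checks. CIS1 was not found among the names of the table.

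Named genes followed a rule written before the data were examined. In each of the 5 comparisons, among genes with adjusted p under 0.05, a change of at least 2-fold, no overlap of values between the groups and a mean of at least 5 RPKM in the higher group, the 8 largest rises and the 8 largest falls were named (for the difference of responses, without the condition on overlap). Every library of one group therefore lay above every library of the other for a gene ranked in any comparison but the difference. Up to 4 members per list with the smallest adjusted p were added, along with SLT2, 4 markers, CRH1, UTR2, CRR1 and GAS1. SLT2, markers, Ty genes (89) and genes of non-coding RNA were kept out of the ranking. Members named because a list had 5 or fewer calls, and YMR295C, were chosen after their values were seen. The table held 6692 protein-coding genes, 299 tRNA, 77 snoRNA, 21 pseudogene, 16 rRNA, 15 ncRNA and 6 snRNA genes. RefSeq held 6048 of the IDs, 6036 at the same coordinates and 5787 with the same symbol.

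The labels say that each biological sample was used without and with the compound, so replicate numbers were taken as pairs within a strain for the blocked fits. Correlations of same-numbered deviations were −0.14, 0.27 and −0.03 in wild type and 0.03, 0.23 and 0.33 in slt2, across genes, which are not independent. In wild type, untreated replicate 1 with treated 3, and untreated 3 with treated 1, each gave 0.23. Further different-numbered values were −0.18 to −0.11 in wild type and −0.35 to 0.19 in slt2. The wild-type numbers may therefore not be the pairs, and all blocked results rest on them. Between strains a number is only a name.

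A self-test simulated negative binomial reads at the depth of each library from the mean of each gene, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. The fit found 98% (wild-type response), 96% (slt2 response), 75% (difference), 95% (untreated) and 96% (treated) of the 2-fold genes and 100% of the 4-fold genes, all with the right sign, with 3, 11, 14, 5 and 11 false calls. Every comparison was simulated with the same dispersion (0.014), whereas real replicates were uneven (chi-square per degree of freedom 4.8 to 101.5). These shares check that the fit works and do not measure its power on the real libraries. The scripts ran with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.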

Results

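Budding yeast of the BY4741 background, either wild type or lacking the cell wall integrity MAP kinase gene SLT2, were compared with and without 1 h of 100 µg/ml poacic acid, a compound that interferes with the cell wall. Each of the 4 groups held 3 libraries (n = 3). Per the labels these are separate biological samples within a group, and each sample was used without and with the compound. The libraries fitted their strain labels. SLT2 (R64 VIII 168890–170344, minus strand) read 46 ± 4.0 RPKM in untreated wild type (mean ± SD), while 4 slt2 libraries held 0 reads of it and the other 2 held 1 read each (0.198 and 0.145 RPKM, under their 3-read floors of 0.596 and 0.433). The auxotrophic markers of BY4741 were near absent in both strains. LEU2 had 0 reads in all 12 libraries, MET17 had 1 read in a single wild-type library (0.134 RPKM), and URA3 had 4 reads (0.647 RPKM, floor 0.485) in treated slt2 replicate 1 and 0 elsewhere. HIS3 read 39.1 to 75.0 RPKM and, being a partial deletion, checks nothing.

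**Figure D1:**
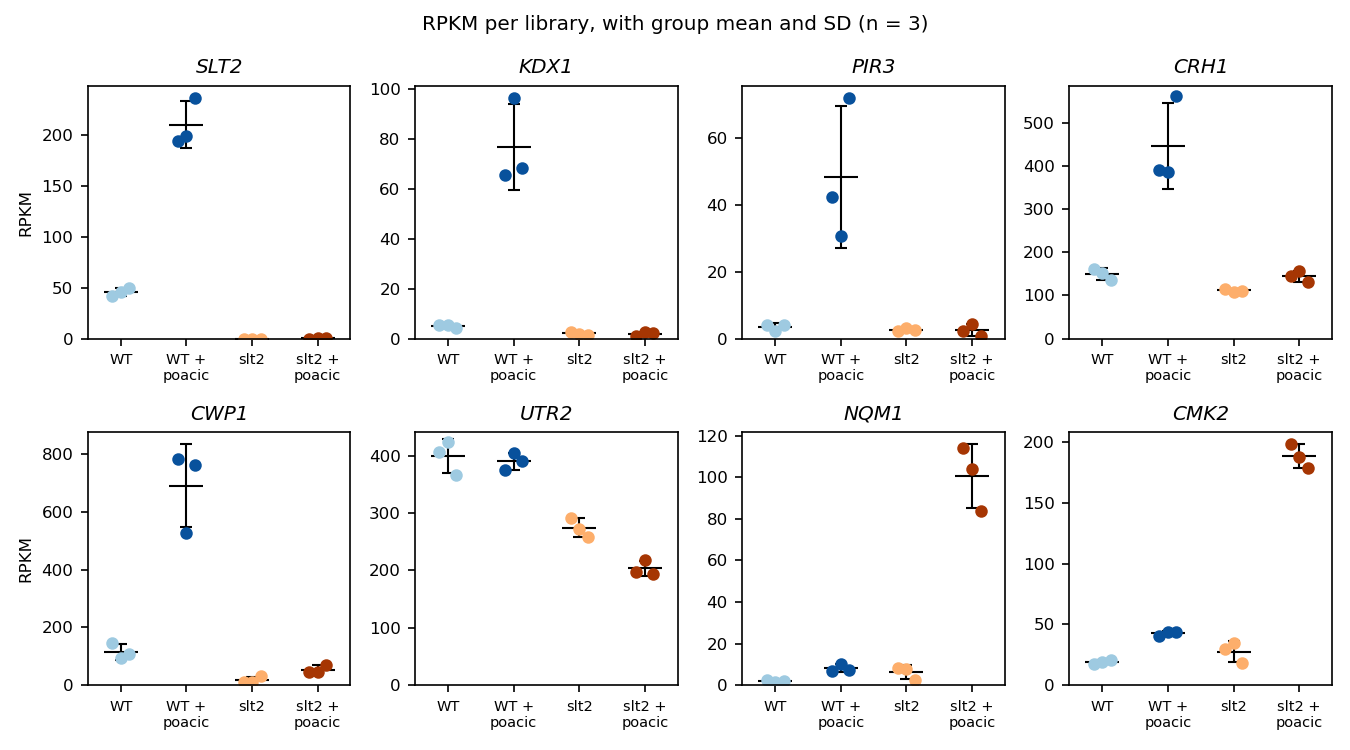
RPKM of 8 genes in wild type (WT) and slt2 cells with and without poacic acid, on linear axes from 0; dots are libraries, horizontal lines are means and error bars are SD (n = 3 per group). KDX1 went from 4.94 to 76.8 RPKM with the compound in wild type and stayed near 2 in slt2 (2.03 and 1.91), while CMK2 reached 189 RPKM in treated slt2 cells and 42.6 in treated wild type.

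Genes of the cell wall integrity pathway rose with poacic acid in wild-type cells. KDX1, which encodes a pseudokinase related to Slt2 (XI 149386–150687, minus strand), rose from 4.94 ± 0.78 to 76.8 ± 17 RPKM. PIR3, which encodes a wall protein bound covalently to glucan (XI 144401–145378, plus strand), rose from 3.55 ± 1.0 to 48.4 ± 21 RPKM. SLT2 itself rose from 46 ± 4.0 to 210 ± 23 RPKM, a log2 fold change of 2.16 (adjusted p = 1.95e-06, limma with Benjamini-Hochberg correction). Of 23 tested targets of Slt2 and the transcription factor Rlm1 (SLT2 is left out of its own lists), 22 rose, and the median log2 fold change was 1.50. PIR1, another glucan-bound wall protein gene, was the member that did not pass (520 ± 27 and 582 ± 130 RPKM, log2 fold change 0.14, adjusted p = 0.647). The largest ranked rises were KDX1 (3.70, adjusted p = 1.3e-06), the putative alcohol dehydrogenase gene YPL088W (6.87 ± 0.74 to 91.0 ± 14 RPKM, 3.54, adjusted p = 1.95e-06), YKL102C (1.44 ± 0.37 to 27.8 ± 6.8 RPKM, 3.54) and PIR3 (3.38). They were followed by the cell cycle regulator gene SRL3 (14.3 ± 0.92 to 128 ± 38 RPKM, 3.04), HHY1 (2.91), YBR056W-A (2.67) and YLR194C, a wall protein gene also named NCW2 (47.6 ± 2.4 to 329 ± 190 RPKM, 2.60). YKL102C (306 bp) and HHY1 were near the floor without the compound, and YBR056W-A overlaps YBR056C-B on the other strand.

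Some wall polysaccharide genes rose with them. Among 15 chitin genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.57. GFA1, whose enzyme makes the sugar precursor of chitin (XI 243220–245373, minus strand), rose from 132 ± 11 to 416 ± 46 RPKM (1.65, adjusted p = 1.95e-06, limma with Benjamini-Hochberg correction). PCM1 rose as well (96.0 ± 4.8 to 240 ± 22 RPKM, 1.31). So did the chitin synthase III gene CHS3 (II 284428–287925, minus strand; 55.9 ± 2.7 to 108 ± 13 RPKM, 0.93) and CHS7, which encodes its export chaperone (42.9 ± 2.0 to 85.1 ± 8.3 RPKM, 0.97). The 16 glucan synthesis genes gave 5 higher and 0 lower (9 and 0 adjusted over the list alone), led by the glucan synthase subunit gene GSC2 (10.8 ± 0.79 to 32.5 ± 11 RPKM, 1.45, adjusted p = 0.000326). Of 38 wall protein genes 14 rose and 1 fell (14 and 3 adjusted over the list alone, 15 and 4 with replicates blocked). SED1 went from 665 ± 77 to 2580 ± 690 RPKM (1.92) and YPS3 rose by 2.10. The cold-shock mannoprotein gene TIR1 fell from 142 ± 34 to 70.1 ± 22 RPKM (−1.03, adjusted p = 0.0101, or 0.0538 without untreated wild-type replicate 1). Of 26 signalling genes of the pathway 7 rose and 0 fell (9 and 0 adjusted over the list alone). Among them were the phosphatase genes PTP2 (9.85 ± 1.9 to 29.7 ± 5.7 RPKM, 1.50) and MSG5 (25.2 ± 0.3 to 56.9 ± 8.9 RPKM, 1.13) and RLM1 (27.9 ± 1.9 to 68.0 ± 13 RPKM, 1.24).

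The crosslinking enzymes of the wall did not move together. CRH1 (VII 876669–878192, minus strand), a transglycosylase that joins chitin to glucan, rose from 150 ± 13 to 447 ± 100 RPKM (1.55, adjusted p = 2.2e-05, limma with Benjamini-Hochberg correction). Its relatives UTR2 (V 78053–79456, plus strand; 399 ± 30 and 391 ± 15 RPKM, −0.03, adjusted p = 0.902) and CRR1 (XII 566654–567922, minus strand; 14.7 ± 2.2 and 15.3 ± 1.8 RPKM, 0.06, adjusted p = 0.859) did not pass. Neither did the glucan elongase gene GAS1 (XIII 887003–888682, plus strand; 814 ± 54 and 836 ± 94 RPKM, 0.03, adjusted p = 0.906). Of 20 wall remodelling genes 5 rose and 1 fell (7 and 3 adjusted over the list alone, 6 and 2 with replicates blocked). The 5 were CRH1, DFG5 (42.3 ± 5.2 to 149 ± 44 RPKM, 1.76), EXG2 (0.95), BGL2 (450 ± 72 to 788 ± 77 RPKM, 0.81) and EXG1 (351 ± 22 to 614 ± 66 RPKM). SCW11, a glucanase gene, fell (57.3 to 36.6 RPKM, −0.63, adjusted p = 0.0108, or 0.0552 without untreated wild-type replicate 1).

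Some secretory and calcium-response genes also rose in wild type, and some ribosome-making genes fell. Of 14 genes of the unfolded protein response 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them the chaperone gene KAR2 (435 ± 57 to 768 ± 100 RPKM, 0.82) and the oxidase gene ERO1 (62.5 ± 2.5 to 118 ± 27 RPKM, 0.88). Of 8 calcineurin targets 4 rose: GSC2, the calmodulin kinase gene CMK2 (XV 294777–296120, minus strand; 19.2 ± 1.6 to 42.6 ± 1.8 RPKM, 1.12, adjusted p = 0.00236, limma with Benjamini-Hochberg correction), RCN2 and PMC1. The rise of RCN2 was 0.95 ( adjusted p = 0.00963, or 0.052 without untreated wild-type replicate 1) and that of PMC1 0.64 (adjusted p = 0.0403, at most 0.15 with a library left out). Adjusted over the list alone there were 6. Of 65 ribosome biogenesis genes 0 rose and 21 fell (0 and 43 adjusted over the list alone, 0 and 34 with replicates blocked), with UTP20 going from 65.3 to 35.8 RPKM (−0.88, adjusted p = 0.007). Of 138 ribosomal protein genes 6 fell by the test over all genes, 57 adjusted over the list alone and 65 with replicates blocked, and many of these genes are near-identical pairs. The largest falls were YLR112W (9.98 ± 0.53 to 3.04 ± 1.2 RPKM, −1.49), the oligopeptide transporter gene OPT1 (X 33850–36249, minus strand; 65.6 ± 7.8 to 29.2 ± 2.1 RPKM, −1.14, adjusted p = 4.53e-05), NCE102 (188 ± 38 to 88.7 ± 6.0 RPKM, −1.06) and SHU2 (−1.14, adjusted p = 0.0482, but 0.197 with a library left out).

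In all, 363 of 6222 tested genes passed adjusted p < 0.05 in wild type (limma with Benjamini-Hochberg correction), 241 higher and 122 lower, of which 93 and 6 changed at least 2-fold. Tested against all other genes with a preset correlation, 16 of 29 lists changed, and the Slt2 and Rlm1 targets (adjusted p = 2.63e-29) were the only one to pass with an estimated correlation (0.00304). The rest lost the call: chitin (1.11e-07; adjusted p = 0.0641 with an estimated correlation), unfolded protein response (1.13e-07; adjusted p = 0.0858 with an estimated correlation), and ribosome biogenesis (8.51e-22; adjusted p = 0.0858 with an estimated correlation). So did glucan synthesis (1.48e-06; adjusted p = 0.16 with an estimated correlation), and ribosomal proteins (1.06e-23; adjusted p = 0.262 with an estimated correlation). Further calls lost were calcineurin targets (0.000131; adjusted p = 0.225 with an estimated correlation), pathway signalling (0.00154; adjusted p = 0.262 with an estimated correlation) and wall proteins (0.000313; adjusted p = 0.474 with an estimated correlation). Wall remodelling did not pass (adjusted p = 0.118). By fry the unadjusted p was 1.38e-06 for chitin, 0.0148 for ribosomal proteins, 0.0104 for wall proteins and 0.166 for general stress. Left-out libraries moved the count of 363 to 164 (untreated wild-type replicate 1), 156 (untreated replicate 2), 552 (treated replicate 2) or 171 (treated replicate 3). Of the named calls, 40 of 70 held in every such fit. Other fits gave 671 genes with replicates blocked, 181 with only the wild-type libraries, 682 with library weights and 232 with rRNA share as a covariate.

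Without SLT2 the cells still responded, and with other genes on top. CMK2 rose from 27.4 ± 8.7 to 189 ± 9.7 RPKM, a log2 fold change of 2.79 (adjusted p = 1.9e-06, limma with Benjamini-Hochberg correction). ENA1, a sodium pump gene controlled by calcineurin (IV 535192–538467, minus strand), rose from 51.8 ± 15 to 336 ± 79 RPKM (2.69, adjusted p = 6.79e-06), although its tandem copies make the value uncertain. All 8 calcineurin targets rose (8 adjusted over the list alone; median 2.05), including RCN1 (16.7 ± 2.4 to 78.2 ± 9.4 RPKM, 2.16) and GSC2 (19.3 ± 1.1 to 109 ± 11 RPKM, 2.43). Of 17 sulfur assimilation genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.89. MET14, the adenylylsulfate kinase gene (XI 438777–439385, minus strand), went from 20.4 ± 3.8 to 84.4 ± 7.8 RPKM (2.01), MET3 from 15.8 ± 2.6 to 52.3 ± 4.9 (1.68) and STR3 from 3.55 to 22.0 ± 3.2 (2.33).

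Most osmotic and general stress genes rose in slt2 cells, and a few in wild type. The difference of responses itself passed for 5 of 18 osmostress genes and 1 of 33 general stress genes. These were 8 and 6 adjusted over the list alone, and 7 and 4 with replicates blocked. The lists share members, so their counts are not separate. The general stress call was CTT1, also among the 5 osmostress calls, and ENA1 of those 5 is also a calcineurin target. Of 18 osmostress genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.69. NQM1, a transaldolase gene (VII 580435–581436, minus strand), went from 6.26 ± 3.3 to 101 ± 15 RPKM (3.93, adjusted p = 7.05e-06, limma with Benjamini-Hochberg correction). RTC3 went from 18.5 ± 0.71 to 169 ± 53 (3.07) and the glycerol synthesis gene GPD1 from 113 ± 31 to 545 ± 96 (2.28). Of 33 general stress genes 18 rose and 0 fell (28 and 0 adjusted over the list alone). The catalase gene CTT1 read 4.42 and 18.1 ± 3.4 RPKM (1.83) and MSC1 20.9 and 91.0 ± 31 RPKM (2.02). The membrane protein gene HSP12 (VI 107256–107585, plus strand) went from 30.1 ± 20 to 309 ± 120 RPKM (3.55, adjusted p = 0.0116, or 0.0572 without treated slt2 replicate 1). In wild type 3 osmostress genes rose (9 adjusted over the list alone, 6 with replicates blocked): NQM1 (1.62, adjusted p = 0.00839), GPD1 (0.00888, or 0.052 without untreated wild-type replicate 2) and RTC3 (0.0195, or 0.0775 without treated wild-type replicate 3). There 2 general stress genes rose (2 adjusted over the list alone, 5 with replicates blocked): NTH1 (1.00, adjusted p = 0.00505) and PNC1 (0.0399, or 0.166 without untreated wild-type replicate 2). Other large rises in slt2 were TMA10 (3.43), YBR056W-A (3.21), FMP45 (13.8 ± 5.3 to 126 ± 43 RPKM, 3.10), SPG4 (3.08) and YPR145C-A (3.07), the last a pair near the floor without the compound.

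The wall target genes split in slt2 cells. Of the 23 Slt2 and Rlm1 targets 6 rose and 4 fell (10 and 4 adjusted over the list alone), with a median log2 fold change of 0.35. The aspartyl protease gene YPS1 (68.1 ± 13 to 292 ± 24 RPKM, 2.10) and PUN1 (35.1 ± 6.9 to 220 ± 36 RPKM, 2.62) rose along with CWP1 (XI 261132–261851, plus strand; 17.3 ± 11 to 53.5 ± 15 RPKM, 1.71), YLR194C, YMR295C and DFG5. PIR1 (XI 141794–142819, minus strand) fell from 500 ± 21 to 176 ± 13 RPKM (−1.51, adjusted p = 2.15e-05, limma with Benjamini-Hochberg correction). HSP150 (864 ± 89 to 434 ± 60 RPKM), PST1 (31.2 ± 6.5 to 12.9 ± 4.7 RPKM) and YNL058C (23.9 ± 1.1 to 11.7 ± 1.6 RPKM) fell too. CRH1 did not pass (112 ± 3.8 and 145 ± 13 RPKM, 0.36, adjusted p = 0.143), nor did CRR1 (0.15, adjusted p = 0.604) or GAS1 (0.08, adjusted p = 0.787). UTR2 fell from 275 ± 16 to 203 ± 13 RPKM (−0.43, adjusted p = 0.0196, but 0.088 without treated slt2 replicate 1). Among chitin genes CHS1 (31.6 to 58.5 RPKM, 0.86) and BUD7 (0.48, adjusted p = 0.0345, at most 0.144 with a library left out) rose (2 adjusted over the list alone). GFA1 read 79.7 ± 2.8 and 63.3 ± 4.6 RPKM (−0.33, adjusted p = 0.0957). Wall proteins gave 6 higher and 5 lower (7 and 5 adjusted over the list alone), with a mean of 0.13 where the test pointed down (adjusted p = 0.974).

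Some ribosome assembly genes and a few G1/S genes fell in slt2 cells. The mating-type switching gene HO fell from 43.5 ± 7.0 to 13.6 ± 0.72 RPKM (−1.60). Of 65 ribosome biogenesis genes 31 fell (53 adjusted over the list alone), NSR1 among them (491 to 293 RPKM, −0.74). Of 20 G1/S genes 4 fell (9 adjusted over the list alone): RNR1 (168 to 106 RPKM, −0.66), CLN2, POL12 and POL1. The last 3 reached adjusted p of 0.132, 0.137 and 0.193 at most with a library left out, and POL1 lost its call with replicates blocked (0.0667).

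Of 6222 genes 526 passed in slt2 (limma with Benjamini-Hochberg correction), 329 higher and 197 lower, and 154 and 24 of them changed at least 2-fold. Of 29 lists 12 changed. Calcineurin targets (adjusted p = 4.77e-14, 0.0335 with an estimated correlation) and sulfur assimilation (5.73e-17, 0.0335) were among those that passed both ways. Calls lost were osmostress (9.86e-18; adjusted p = 0.0735 with an estimated correlation), ribosome biogenesis (1.39e-26; adjusted p = 0.062 with an estimated correlation), general stress (4.24e-15; adjusted p = 0.365 with an estimated correlation) and G1/S (0.000548; adjusted p = 0.445 with an estimated correlation). The Slt2 and Rlm1 targets did not pass as a list by camera (adjusted p = 0.101), and neither did chitin (0.974). By fry the unadjusted p was 0.0159 for these targets, 0.37 for chitin and 2.67e-05 for osmostress. Left-out libraries moved the count of 526 to 347 (untreated slt2 replicate 1), 240 (untreated replicate 3), 280 (treated replicate 1) or 231 (treated replicate 2). Of the named calls, 54 of 81 held in every such fit. Library weights gave 1137 genes.

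The strains shared part of the response and differed in a set of genes that went both ways. The difference of responses (slt2 minus wild type) passed for 107 genes, 45 higher and 62 lower (limma with Benjamini-Hochberg correction). KDX1 differed most, with a log2 difference of −3.77 (adjusted p = 3.33e-05). It was followed by YKL102C (−3.74), PIR3 (−3.55, adjusted p = 0.00218), YNL057W (−3.33), YPL088W (−3.20), PST1 (−2.79, adjusted p = 0.000467), CRG1 (−2.58, adjusted p = 0.0192, or 0.0546 without untreated wild-type replicate 1) and YMR103C (−2.55). YNL057W overlaps YNL058C (XIV 515763–516713, minus strand) on the other strand. Of 23 Slt2 and Rlm1 targets 13 responded less in slt2 and 1, PUN1 (1.26, adjusted p = 0.0246), responded more (17 and 2 adjusted over the list alone; median −1.08). PST1, HSP150 (−2.12) and YNL058C (−2.52) rose in wild type and fell in slt2, and PIR1 (−1.64, adjusted p = 0.000733) fell in slt2 alone. CRH1 responded less in slt2 (−1.19, adjusted p = 0.00645), whereas UTR2 (−0.40, adjusted p = 0.257), CRR1 (0.09, adjusted p = 0.897) and GAS1 (0.04, adjusted p = 0.948) did not pass. The chitin genes gave 0 higher and 4 lower (0 and 6 adjusted over the list alone; median −0.32): GFA1 (−1.98, adjusted p = 3.33e-05), PCM1 (−1.20), CHS7 (−1.17) and CHS3 (−0.85). RLM1 (−1.18, adjusted p = 0.0136) and MSG5 (−1.18, adjusted p = 0.00482) joined KDX1 among the pathway genes. PTP2 did not pass (−0.94, adjusted p = 0.0785, or 0.0373 with replicates blocked).

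**Figure D2:**
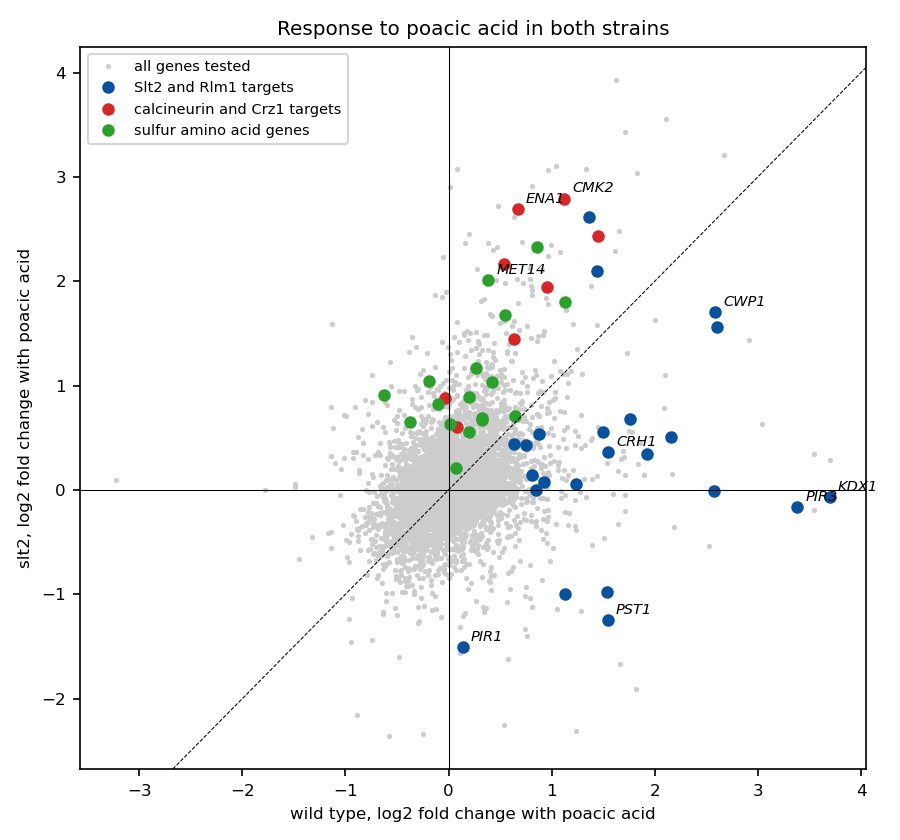
Log2 fold change with poacic acid in wild type (x axis) and in slt2 (y axis) for 6222 genes (grey), n = 3 libraries per group, with equality dashed; Slt2 and Rlm1 targets are blue, calcineurin targets red and sulfur genes green. Blue points lay mostly under the line (median difference −1.08), and red (0.99) and green (0.69) points mostly above it.

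Of the 45 genes above wild type in this test, 9 were sulfur genes and 3 calcineurin targets. Sulfur genes gave 9 higher and 0 lower (10 and 0 adjusted over the list alone; median 0.69). In wild type 3 sulfur genes rose and 1 fell (4 and 1 adjusted over the list alone; median 0.26). STR3 (adjusted p = 0.0258), MET3 (0.0394) and MET28 (0.049) rose there, at 0.109, 0.137 and 0.205 at most with a library left out, and MET28 lost its call with replicates blocked (0.0621). MET6, the methionine synthase gene, fell in wild type (205 ± 16 to 133 ± 13 RPKM, −0.62, adjusted p = 0.0168, or 0.0735 without untreated replicate 1) and rose in slt2 (196 ± 21 to 370 ± 61 RPKM), a log2 difference of 1.53 (adjusted p = 0.00075, limma with Benjamini-Hochberg correction). MET14 (1.62, adjusted p = 0.00218) and MET10 (1.23, adjusted p = 0.00616) differed the same way. Of 8 calcineurin targets 3 passed (8 adjusted over the list alone; 5 with replicates blocked; median 0.99): ENA1 (2.02, adjusted p = 0.00218), RCN1 (1.63) and CMK2 (1.68, adjusted p = 0.00325). Osmostress genes gave 5 higher (8 adjusted over the list alone; median 1.16): ENA1, the aldehyde dehydrogenase gene ALD3 (1.55, adjusted p = 0.0045), NQM1 (2.31, adjusted p = 0.0163, or 0.0535 without untreated wild-type replicate 1), CTT1 (1.48, adjusted p = 0.0175, or 0.0662 without treated slt2 replicate 2) and GRE2 (0.90). The proline oxidase gene PUT1 (XII 425186–426616, plus strand) read 3.25 and 3.32 RPKM in wild type and went from 4.75 ± 1.9 to 41.4 ± 12 in slt2 (2.89, adjusted p = 0.0011). The decarboxylase gene ARO10 went from 13.4 ± 3.6 to 92.8 ± 12 RPKM in slt2 (2.24, adjusted p = 0.00166). FMP48 (2.26), HXT2 (1.23, adjusted p = 0.0109), SPG4 (2.99), PDC6 (2.29) and PHM7 (2.11) also passed. The last 3 lost the call with a library left out, at adjusted p = 0.117, 0.0995 and 0.0952 at most. HSP12 did not pass (1.44, adjusted p = 0.621), and in wild type it read 7.35 ± 3.2 and 36.6 ± 20 RPKM (2.11, adjusted p = 0.109).

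**Figure D3:**
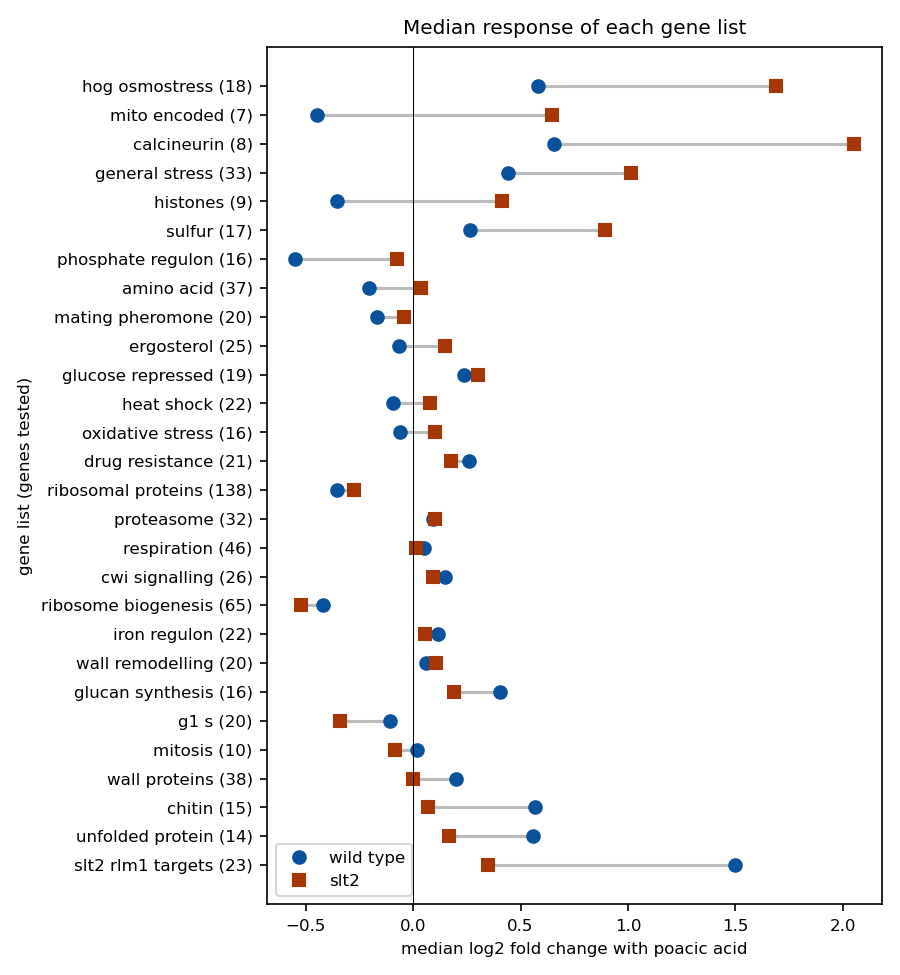
Median log2 fold change with poacic acid of each of 28 gene lists in wild type (circles) and slt2 (squares), sorted by the median difference; tested genes are in brackets and n = 3 libraries per group. Slt2 and Rlm1 targets stood at 1.50 and 0.35, calcineurin targets at 0.65 and 2.05.

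Both responses called 113 genes in the same direction, 68 higher (12.7 by chance) and 45 lower (3.9 by chance), and 5 in opposite directions. The responses compare different libraries with no shared controls, and their fold changes correlated with r = 0.36 across genes, which are not independent. Of the 241 genes that rose in wild type, chosen on that response, 59 passed the difference test and 53 of them moved toward a smaller response in slt2 (medians 0.90 and 0.31). Of the 329 that rose in slt2, 43 passed and 41 had the smaller response in wild type (0.96 and 0.38). By lists tested with a preset correlation 17 of 29 differed (limma with Benjamini-Hochberg correction), and only the Slt2 and Rlm1 targets (adjusted p = 7.99e-20, 0.0118 with an estimated correlation) passed both ways. Lost calls were sulfur (1.66e-13; adjusted p = 0.0556 with an estimated correlation) and chitin (4e-07; adjusted p = 0.0556 with an estimated correlation). Others were calcineurin targets (adjusted p = 2.13e-10, or 0.0574 with an estimated correlation) and osmostress (adjusted p = 1.08e-10, or 0.153 with an estimated correlation). By fry the unadjusted p of the difference was 3.52e-05 for chitin, 0.000173 for sulfur and 0.000307 for calcineurin targets. For osmostress it was 0.0062, for general stress 0.116 and for phosphate 0.37. Left-out libraries moved the difference count of 107 to 70 (untreated wild-type replicate 1), 164 (treated wild-type replicate 2) or 62 (treated slt2 replicate 2). Blocking gave 179 and library weights 289. The split of 45 higher and 62 lower turned to 92 and 72 without treated wild-type replicate 2. With blocking the split was 96 and 83, and with library weights 163 and 126. The overlap of 113 became 56 and 45 without untreated wild-type replicates 1 and 2, 67 without treated wild-type replicate 3, 73, 72 and 65 without untreated slt2 replicates 1, 2 and 3, and 54 without treated slt2 replicate 1 or 2. It was 228 with blocking, 258 with library weights and 58 with only the groups compared.

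Without the compound, wall genes were among those that differed between the strains. CWP1, a mannoprotein gene of the wall, read 115 ± 28 RPKM in wild type and 17.3 ± 11 in slt2, a log2 difference of −2.80 (adjusted p = 0.00817, limma with Benjamini-Hochberg correction). Of 23 Slt2 and Rlm1 targets 0 were higher and 6 lower in slt2 (0 and 8 adjusted over the list alone; median −0.35), SED1 (346 ± 58 RPKM in slt2, −0.95, adjusted p = 0.0421), PRM5 (34.8 ± 4.9 and 13.4 ± 5.5 RPKM, −1.38, adjusted p = 0.0288) and KDX1 (−0.98, adjusted p = 0.044) among them. GFA1 was the only chitin gene lower (−0.72, adjusted p = 0.0194; 4 adjusted over the list alone). CHS3 stopped just short (40.1 ± 1.5 RPKM in slt2, −0.47, adjusted p = 0.0514). UTR2 was lower (−0.54, adjusted p = 0.0309, but 0.0511 after median scaling). CRH1 (−0.41, adjusted p = 0.113), CRR1 (−0.05, adjusted p = 0.861) and GAS1 (673 ± 71 RPKM in slt2, −0.28, adjusted p = 0.182) did not pass. YJL133C-A, also named DPI8 (X 159623–159847, minus strand), was higher in slt2 (22.4 ± 1.5 and 62.6 ± 9.5 RPKM, 1.44, adjusted p = 0.00352). So were LSO1 (0.96 ± 0.30 and 5.66 ± 0.87 RPKM, 1.77) and YGR259C, which overlaps TNA1 on the other strand (6.96 ± 8.8 and 82.9 ± 16 RPKM, 4.20, adjusted p = 0.0434). The agglutinin anchor gene AGA1 was lower (21.2 ± 5.3 and 5.20 ± 1.2 RPKM, −1.83, adjusted p = 0.0376). Of 138 ribosomal protein genes RPS16A (1080 ± 120 and 533 ± 95 RPKM, −1.03), RPL30, RPL22B and RPS17B were lower (1 higher and 10 lower adjusted over the list alone). HAC1, the regulator of the unfolded protein response, was higher (996 ± 120 and 1680 ± 210 RPKM, 0.75, adjusted p = 0.0309).

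The untreated difference passed for 109 of 6222 genes, 55 higher and 54 lower in slt2 (limma with Benjamini-Hochberg correction), and 34 of them overlap a gene on the other strand. Of the called genes 50.5% were higher in slt2, a share that became 63.1% with quantile normalization and 68.3% with median scaling. The median log2 difference over all tested genes was −0.081. Reads in rRNA genes made up 0.40 ± 0.33% of listed reads in untreated wild type and 5.58 ± 0.94% in untreated slt2. With that share as a covariate only 1 gene passed (SLT2), with CWP1 at adjusted p = 0.13 and YJL133C-A at 0.251. The lists called with a preset correlation numbered 11 and 0 with an estimated one (all at adjusted p of 0.893 or more with an estimated correlation), among them Slt2 and Rlm1 targets (0.00474), mating genes (0.000774, median −0.62) and the iron regulon (0.000156, median 0.52). Osmostress (0.00474, median 0.32) and general stress (0.00287, median 0.18) were also called by camera as higher in slt2, though no single member passed. The count of 109 became 6, 13 and 45 without untreated wild-type replicates 1, 2 and 3, and 3, 5 and 39 without untreated slt2 replicates 1, 2 and 3. It became 483 and 604 without treated wild-type replicates 2 and 3, and 69 and 63 without treated slt2 replicates 1 and 2. SLT2 and YJL133C-A alone of 31 named calls held in every such fit, and CWP1 lost its call only without untreated slt2 replicate 1. Fits of only the groups compared and with library weights gave 729 and 1142 genes.

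With the compound, wall genes differed between the strains as well. KDX1 read 76.8 ± 17 RPKM in wild type and 1.91 ± 0.64 in slt2, a log2 difference of −4.74 (adjusted p = 1.63e-08, limma with Benjamini-Hochberg correction). GFA1 read 416 ± 46 and 63.3 ± 4.6 RPKM (−2.69, adjusted p = 5.62e-09), and CRH1 447 ± 100 and 145 ± 13 (−1.60, adjusted p = 5.78e-06). UTR2 was lower in slt2 as well (391 ± 15 and 203 ± 13 RPKM, −0.94, adjusted p = 4.07e-05), whereas CRR1 (0.04, adjusted p = 0.898) and GAS1 (−0.24, adjusted p = 0.268) did not pass. Of 23 Slt2 and Rlm1 targets 18 were lower and 2, PUN1 (1.43) and YPS1 (1.01), higher (18 and 2 adjusted over the list alone; median −1.60). Of 15 chitin genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone). Among them were CHS3 (−1.32, adjusted p = 4.47e-06), PCM1 (−1.54) and CHS7 (−1.40). The other large differences below wild type were YKL102C (−4.40), PIR3 (−3.84), SRL3 (−3.72), CWP1 (−3.68), CRG1 (−3.42), YPL088W (−3.40) and PST1 (−3.33). Some secretory genes were lower in slt2, with 6 of 14 unfolded protein genes passing (8 lower and 1 higher adjusted over the list alone), KAR2 (−0.78) and ERO1 (−0.98) among them.

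Most calcineurin, sulfur and osmostress genes and some general stress genes stood higher in treated slt2 cells. Calcineurin targets gave 7 of 8 higher (8 adjusted over the list alone; median 1.54), with ENA1 at 2.46 and CMK2 at 2.12 (adjusted p = 4.91e-06 for both, limma with Benjamini-Hochberg correction). Sulfur genes gave 12 of 17 higher (15 adjusted over the list alone), STR3 (2.38) and MET6 (1.46) among them. Osmostress genes gave 12 of 18 (14 adjusted over the list alone), led by NQM1 (3.50, adjusted p = 7.12e-06). General stress genes gave 14 of 33 higher (24 higher and 1 lower adjusted over the list alone). HSP12 was higher (3.10, adjusted p = 0.0201, or 0.0895 without treated slt2 replicate 1 and 0.0648 with the rRNA covariate). Of 37 amino acid synthesis genes 9 were higher and 0 lower (12 and 1 adjusted over the list alone), HIS4 (0.82) and SER3 (0.64) among them. Large single differences were YPR145C-A (4.08), SPG4 (3.90), FMP45 (3.41), PUT1 (3.27, adjusted p = 4.47e-06), TMA10 (3.09, adjusted p = 0.012, or 0.0509 without treated slt2 replicate 1) and PHM7 (2.73).

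The treated difference passed for 511 of 6222 genes, 248 higher and 263 lower in slt2 (limma with Benjamini-Hochberg correction), and 123 and 101 of them at least 2-fold. Over all tested genes the median log2 difference was −0.065, and the split by direction depended on the scaling. It became 299 higher and 270 lower with quantile normalization, and 320 and 228 with median scaling. Of the 29 lists 23 differed with a preset correlation and 6 with an estimated one. These included Slt2 and Rlm1 targets (adjusted p = 6.89e-19, 0.0138 with an estimated correlation), chitin (5.67e-08, 0.0306), calcineurin targets (2.97e-12, 0.0306), sulfur (7.02e-17, 0.0306) and amino acid synthesis (4.29e-08, 0.0306). Osmostress (1.05e-16; adjusted p = 0.0623 with an estimated correlation), general stress (7.6e-15; adjusted p = 0.24 with an estimated correlation) and the unfolded protein response (0.000546; adjusted p = 0.235 with an estimated correlation) lost the call. The rRNA share was 2.64 ± 2.52% in treated wild type, where single libraries read 2.67, 0.11 and 5.15%, and 6.17 ± 0.16% in treated slt2. Left-out libraries moved the count of 511 to 874 (treated wild-type replicate 3), 327 (treated slt2 replicate 1) or 334 (treated slt2 replicate 2). Of the named calls, 68 of 97 held in every such fit. Fits of only the groups compared and with library weights gave 330 and 1375 genes. The order of the strain comparisons (511 treated and 109 untreated) turned when only the groups compared were fitted (330 and 729) and without treated wild-type replicate 2 (402 and 483).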

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

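The tests of explanations below were chosen after the results were seen, while the test of the difference between the responses of the strains was planned. The response to poacic acid differed between wild type and slt2 for 107 genes by that test (limma on the difference, Benjamini-Hochberg correction). The log2 differences (slt2 minus wild type) of the named genes with a smaller or opposite response in slt2 were −3.767 for KDX1, −3.737 for YKL102C, −3.547 for PIR3, −3.33 for YNL057W, −3.195 for YPL088W, −2.792 for PST1, −2.579 for CRG1, −2.546 for YMR103C, −2.516 for YNL058C, −2.121 for HSP150, −1.977 for GFA1, −1.644 for PIR1, −1.202 for PCM1, −1.186 for CRH1, −1.184 for RLM1, −1.181 for MSG5, −1.165 for CHS7, −1.079 for DFG5, −1.039 for EXG1, −0.941 for JEM1 and −0.854 for CHS3. Those above wild type were 2.993 for SPG4, 2.888 for PUT1, 2.309 for NQM1, 2.291 for PDC6, 2.257 for FMP48, 2.244 for ARO10, 2.11 for PHM7, 2.022 for ENA1, 1.675 for CMK2, 1.626 for RCN1, 1.623 for MET14, 1.548 for ALD3, 1.529 for MET6, 1.484 for CTT1, 1.23 for HXT2, 1.229 for MET10, 1.123 for QCR8, 1.122 for MET3 and 1.045 for HTB1. Of the 42 named calls of this difference 30 held with any library left out. Those lost in such a fit included CRG1 (adjusted p = 0.0546 without untreated wild-type replicate 1), NQM1 (0.0535 without the same library), CTT1 (0.0662 without treated slt2 replicate 2), EXG1 (0.0627 without untreated slt2 replicate 2), and, at the highest adjusted p of any such fit, HTB1 (0.106), PDC6 (0.0995), QCR8 (0.0925), JEM1 (0.0574), SPG4 (0.117), DFG5 (0.102) and PHM7 (0.0952).

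Lists differed between the strains too, by camera with a preset correlation. Their median log2 differences were −1.079 for Slt2 and Rlm1 targets, −0.379 for the unfolded protein response, −0.317 for chitin, −0.233 for wall proteins, −0.222 for mitosis, −0.101 for wall remodelling and −0.04 for wall integrity signalling (adjusted p = 0.0479, or 0.0787 with replicates blocked). Above wild type were osmostress (1.159), mitochondrially encoded genes (0.993), calcineurin targets (0.987), general stress (0.803), histones (0.738), sulfur (0.694), phosphate (0.583), amino acid synthesis (0.295) and ergosterol (0.226). With an estimated correlation the Slt2 and Rlm1 targets passed (adjusted p = 0.0118). The other lists lost the call. With an estimated correlation their adjusted p was 0.0556 for chitin and sulfur, 0.0574 for calcineurin targets, 0.0578 for amino acid synthesis, 0.153 for osmostress and the unfolded protein response and 0.183 for histones. It was 0.384 for wall remodelling and ergosterol, 0.457 for wall proteins and mitochondrially encoded genes, 0.461 for wall integrity signalling and general stress, 0.466 for mitosis and 0.613 for phosphate.

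The Slt2 and Rlm1 target list responded less in slt2, with a median log2 difference of −1.08. With the rRNA share as a covariate the median was −1.07, so it hardly moved. The bootstrap limits (−1.5 to −0.66) resample genes of the list, not libraries, and leave out the spread between cultures. The covariate rests mostly on treated wild-type replicates 2 and 3, whose log2 shares deviated from their group mean by −3.38 and 2.17. Library composition tied to that share is therefore not excluded. With any 1 treated library left out the median came no nearer 0 than −0.97 (without treated wild-type replicate 3), which argues against a single treated library. Untreated libraries were not left out in turn for this median. The compound did act on slt2 cells, since 526 genes passed there. The list and the test of the difference were fixed beforehand, and the deletion tests a need for Slt2 in the response of these genes. These values go with such a need. It stays a hypothesis, since composition tied to the rRNA share is not excluded and the tests of explanations used the same libraries.

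The sulfur, calcineurin and osmostress lists responded more in slt2, with a median difference of 0.92 over 42 members. The glucose-repressed list, which would rise if sugar ran out, had a median of 0.30 in slt2 (bootstrap limits over its genes 0.15 to 0.56). The members stood at 1.13, but their lists were picked for their rise, so this gap decides nothing. The glucose-repressed list rose as well (camera adjusted p = 0.0118, or 0.613 with an estimated correlation), and 2 of its genes passed. Sugar running out in the medium therefore stays open. A single treated slt2 library is argued against by a lowest median difference of 0.89 with 1 left out (treated slt2 replicate 1). With the rRNA share as a covariate the median was 0.90 (limits 0.71 to 1.14), so it hardly moved. These limits resample genes of the lists, not libraries. The log2 share deviated from its group mean by only −0.18 to 0.27 in slt2 libraries, so the covariate rests mostly on treated wild-type libraries. Library composition tied to that share is therefore not excluded here either. A stronger stress in cells that lack Slt2 stays open as a hypothesis, and no measure of stress other than RNA was used here.

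The rRNA share differed between the untreated strains, as 109 genes did. Within groups, the score of each library along the strain difference and its log2 rRNA share had r = 0.79 over 12 libraries, which did not pass (exact permutation p = 0.174, 1296 permutations; rho = 0.59, p = 0.135; r = 0.22 without treated wild-type replicates 2 and 3). Adding the share to the fit left 1 call, but share and strain go together in the untreated groups, so composition and strain cannot be told apart for these calls. Reads from the opposite strand are argued against as the whole source, since 72 of the 109 genes (66.1%, against 84.1% of all tested) are in RefSeq and overlap no gene on the other strand. These were 47 of the 54 lower calls but 25 of the 55 higher ones, so the argument leaves most higher calls uncovered. A wrong strain label is argued against by SLT2, which read at most 0.198 RPKM in any library labelled slt2 and at least 42.1 in wild type. An effect of the deletion stays open as well.

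Other splits of the same libraries were counted for each comparison, with 10 splits each, too few for a share under 0.05. The real split called 363 genes in the wild-type response and the highest other 2, and these were 526 and 4 in the slt2 response, 107 and 0 for the difference, 109 and 0 untreated and 511 and 2 treated. Only 1 split of 10, the real one, gave as many genes each time. Among splits that part all 3 replicate pairs, as the real one does, the other 3 called 0 genes in either response (limma; the real splits had 1335 and 1392 genes at an unadjusted p under 0.05).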

How the results depend on the processing

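The fits with median scaling, voom on recovered reads, RefSeq genes only, library weights and the rRNA share as a covariate were chosen after seeing the data. The alternatives planned for counts (DESeq2 and its RLE size factors) were not run, since the values are RPKM.

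Fits of only the groups compared called 181 (wild-type response), 729 (untreated) and 330 (treated) genes and an overlap of 58. Blocking by replicate gave 671 (wild-type response), 179 (difference) and an overlap of 228. Library weights gave 682, 1137, 289, 1142 and 1375 genes (wild-type response, slt2 response, difference, untreated, treated) and an overlap of 258. The rRNA covariate gave 232 in the wild-type response, 200 of them shared with the 363, and 1 untreated. The overlap was 31 at adjusted p under 0.01 and 27 at 2-fold or more. Lists called with an estimated correlation fell to 1, 3, 1, 0 and 6. The estimates were 0.059 (amino acid synthesis) to 0.844 (phosphate) against the preset 0.01, and a higher correlation weakens the list test by construction. The stricter thresholds of the overlap also pass fewer genes by construction. For the other changes the cause was not tested. Quantile normalization, no low filter, pseudocounts of 0.1 and 5, median scaling, voom and RefSeq genes only kept each total of called genes within 1.5 times. Of the untreated genes split by direction, the 54 lower became 31 with quantile normalization and 32 with median scaling, and the 55 higher became 36 with RefSeq genes only. With 1 library left out counts ranged from 156 to 552 (wild-type response), 231 to 671 (slt2 response), 62 to 164 (difference), 3 to 604 (untreated) and 327 to 874 (treated), and the overlap from 45 to 140.

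Blocking changed no list call in the slt2 response. It ended that of wall integrity signalling in the difference (adjusted p = 0.0787) and brought in sulfur in the wild-type response (0.0486). Between the strains, where numbers are only names, it gave 122 untreated and 478 treated genes and ended the untreated calls of chitin (0.0763) and ribosome biogenesis (0.0763).

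The 636 results of named genes had 14491 alternative values, of which 13143 stayed on the same side of the threshold, 498 passed it, 850 fell short and 0 turned direction. Only 321 of the 636 results were called, and only these could fall short. Named genes that blocking brought past the threshold included PHO89 in slt2 (1.85, adjusted p = 0.116, blocked 0.000469), PDR5 (0.64, 0.069, blocked 0.0134) and PHO12 (−1.45, 0.229, blocked 8.18e-05) in wild type, and MSC1 in the difference (1.36, 0.0803, blocked 0.0116). Untreated, SED1 lost its call after median scaling (adjusted p = 0.0752) and quantile normalization (0.0669), and NQM1 in the difference with a pseudocount of 0.1 (0.0677) or voom (0.0755). Libraries of 3462651 to 10542488 reads limit genes of low value: 3 reads in a gene of 1 kb are 0.285 to 0.866 RPKM.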

Other observations

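The MCM, ARO, PDC6, FIT and nitrogen genes below were chosen after their values were seen, and so was the test of that list. All 6 genes of the replicative helicase, MCM2 to MCM7, fell with poacic acid in slt2 (log2 fold changes −0.81, −0.75, −0.49, −0.68, −0.61 and −0.92, adjusted p = 0.000887, 0.000407, 0.0231, 0.00793, 0.0103 and 0.000345, limma with Benjamini-Hochberg correction). None passed in wild type, and none passed the test of the difference (MCM2 −0.68, adjusted p = 0.0694). ARO9 and ARO10, which break down aromatic amino acids, and the pyruvate decarboxylase gene PDC6 rose in slt2: ARO9 by 1.90 (adjusted p = 5.35e-05; difference 1.92, 0.00218), ARO10 by 2.73 (7.05e-06) and PDC6 by 2.23 (0.00125). The iron mannoprotein genes FIT1, FIT2 and FIT3 read higher in untreated slt2 by 2.01, 2.30 and 2.43, with standard errors of 0.633, 0.847 and 0.852, and did not pass (adjusted p = 0.104, 0.148 and 0.135).

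Genes for using poor nitrogen sources rose in treated slt2 cells: GAP1 (1.61, adjusted p = 0.00103), MEP1 (1.30, 0.00197), PUT1 (2.90, 1.82e-05), PUT4 (1.92, 4.67e-05), CAR1 (1.15, 2.34e-05), CAR2 (0.82, 0.0104), GDH2 (0.87, 0.0135) and DUR1,2 (1.00, 0.000371). In wild type PUT4 (0.81, adjusted p = 0.0313) and CAR1 (0.50, 0.0198) rose too. By the test of the difference from wild type GAP1 passed (1.53, adjusted p = 0.0386), as did PUT1 (2.89, 0.0011) and DUR1,2 (0.95, 0.0181). MEP1 (0.137; blocked 0.0373), CAR1 (0.0564; blocked 0.0397), PUT4 (0.0751), CAR2 (0.265) and GDH2 (0.121) did not. A release of nitrogen catabolite repression would raise other genes under that control as well. The 19 members of a list of such genes that had not prompted the idea had a median of 0.38, 2 of them rose, and the list test gave p = 0.00614, or 0.255 with an estimated correlation, so the hypothesis stays open.

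Histone genes fell in part in wild type and rose in part in slt2. In wild type 1 of 9 fell (2 with replicates blocked), HTB1 (309 ± 37 to 194 ± 36 RPKM, −0.68, adjusted p = 0.027, or 0.112 without treated wild-type replicate 3; 1 adjusted over the list alone), and the list fell (0.0236; adjusted p = 0.58 with an estimated correlation). In slt2 HHF2 (643 to 951 RPKM, 0.57, adjusted p = 0.00796) and HTA2 (0.82, 0.0218, at most 0.0883 with a library left out) rose (5 adjusted over the list alone, 5 with replicates blocked; list 0.00322; adjusted p = 0.527 with an estimated correlation). The difference test passed for HTB1 (1.04, adjusted p = 0.035, at most 0.106 with a library left out; 7 adjusted over the list alone and 5 with replicates blocked) and for the list (5.91e-06; adjusted p = 0.183 with an estimated correlation). Copies of histone genes are near identical.

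In wild type (limma or camera with Benjamini-Hochberg correction) 0 mating, 0 glucose-repressed, 0 phosphate, 0 drug resistance, 0 oxidative stress, 0 heat shock, 0 ergosterol, 0 proteasome and 0 mitochondrially encoded genes passed over all genes. With replicates blocked, 9 phosphate genes fell, PHO12 (−1.45, adjusted p = 8.18e-05) and VTC3 (−0.80, 0.0215) among them, and 3 drug resistance genes rose: PDR5 (0.64, 0.0134), AZR1 (0.0175) and TPO2 (0.0381). Blocking also brought in AGA1 (lower, 0.0194) and PRM4 (higher, 0.049) of the mating list, HXT5 (higher, 0.0127), GTT2 (higher, 0.0321), SSA2 (lower, 0.0393) and RPT2 (higher, 0.0228) of the glucose-repressed, oxidative stress, heat shock and proteasome lists, and left ergosterol and mitochondrially encoded genes at 0. Respiration gave 3 of 46 higher (CIT1, LSC2 and LSC1, the last 2 at adjusted p = 0.101 and 0.219 at most with a library left out), iron 1 of 22 lower (FRE1, −0.80, adjusted p = 0.0089, or 0.0548 with only the groups compared) and mitosis 1 of 10 higher (MOB1, 0.57, 0.032, at most 0.12 with a library left out). Of these lists, mating (median −0.17, adjusted p = 0.0275; adjusted p = 0.58 with an estimated correlation) and phosphate (−0.55, 0.00123; adjusted p = 0.58 with an estimated correlation) changed. Amino acid synthesis fell (4 of 37 lower, 8 adjusted over the list alone; median −0.21, 1.12e-05; adjusted p = 0.0858 with an estimated correlation), and osmostress (0.58, 1.66e-05; adjusted p = 0.365 with an estimated correlation) and general stress (0.44, 0.000631; adjusted p = 0.58 with an estimated correlation) rose. Lists that did not pass were glucose-repressed (0.241), respiration (0.471), iron (0.68, with a positive median of 0.12 where the test pointed down), drug resistance (0.182), oxidative stress (0.271), heat shock (0.425), G1/S (0.0691), mitosis (0.525), ergosterol (0.102), sulfur (0.0545), proteasome (0.118) and mitochondrially encoded genes (0.241).

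In slt2 amino acid synthesis gave 5 higher (ARG4, SER3, ARG3 and SER33 among them) and 1 lower (ILV5) of 37 (6 and 1 adjusted over the list alone), wall remodelling 2 higher (SCW10, DFG5) and 4 lower (SCW11, DSE4, UTR2, CTS1), glucan synthesis 3 higher (GSC2, KRE6, RHO1) and signalling 2 higher (WSC2, RHO1) and 1 lower (SWI4). With a library left out the adjusted p reached 0.088 for UTR2, 0.123 for RHO1, 0.131 for SWI4, 0.0523 for SER3, 0.117 for ARG3 and 0.129 for SER33. Other lists gave mating 1 higher and 2 lower (PRM4, FAR1 and MFA2), glucose-repressed 2 higher (HXT2 and HXT5), respiration 4 higher (CIT1, QCR8, LSC2 and QCR10), drug resistance 3 higher (RTA1, PDR10 and TPO4), heat shock 3 higher (HSP104, HSP26 and HSP42), mitosis 2 lower (CDC20 and HOF1), and 1 higher each for oxidative stress (TSA2), ergosterol (UPC2), the unfolded protein response (HRD1) and proteasome (RPN2), by limma with Benjamini-Hochberg correction. With a library left out the adjusted p reached 0.0843 for MFA2, 0.0652 for QCR8, 0.193 for LSC2, 0.201 for QCR10, 0.0775 for PDR10 and 0.169 for TPO4. It reached 0.0848 for HSP104, 0.189 for HSP26, 0.169 for HSP42, 0.153 for HOF1, 0.0835 for TSA2, 0.141 for HRD1 and 0.182 for RPN2, and blocking ended the calls of RPN2 (0.0512) and TPO4 (0.0536). FAR1, which arrests the cell cycle on pheromone, fell from 49.7 to 21.8 RPKM (−1.15, adjusted p = 0.000966), and RTA1 rose from 5.02 to 16.5 RPKM (1.51, 0.000769). Glucose-repressed (0.30, adjusted p = 0.0118; adjusted p = 0.613 with an estimated correlation), glucan synthesis (0.19, 0.0248; adjusted p = 0.613 with an estimated correlation), ribosomal protein (−0.28, 2.53e-17; adjusted p = 0.514 with an estimated correlation; 2 of 138 lower over all genes, 0 adjusted over the list alone and 28 with replicates blocked) and mitochondrially encoded lists (0.0248; adjusted p = 0.653 with an estimated correlation) changed. Lists that did not pass were wall integrity signalling (0.18), wall remodelling (0.791, with a median of 0.11 where the test pointed down), mating (0.63), respiration (0.671), iron (0.906), phosphate (0.854), drug resistance (0.16), oxidative stress (0.671), heat shock (0.303), unfolded protein response (0.333), mitosis (0.0604), ergosterol (0.085), amino acid synthesis (0.671) and proteasome (0.218).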
